A study of Homo sapiens with 24 samples.

How the data were processed

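Gene expression was measured in HCT116 cells treated for 72 h with DMSO or with DAC, Aza, G669071, G668684 or G669043, on Affymetrix HG-U133 Plus 2.0 arrays. Per the labels' protocols the cells came from ATCC, were grown in RPMI1640 with 5% FBS, and gave RNA purified with the RNeasy Plus Mini kit. The 24 arrays were grouped by compound and dose as the titles give them, with 4 arrays for DMSO and 2 for each of 10 treated groups. For G669071 the titles and the source names disagree on the dose, and the titles were used. The titles of the G669071 samples hold the word phos, those of G668684 the word ester and those of G669043 the prefix Aza, and no structure or parent drug was taken from them. The source names of the last give the prodrug alone, so it was treated as a single compound.

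The authors computed RMA values in Affymetrix Expression Console 1.1, per the submitters' processing notes. The deposited values are linear intensity values, 1 for each of 54675 probe sets, and their log2 was taken here. The deposited table holds no detection calls, so which genes lie above background is unknown, and a fold against a level under the filter value below has no settled size. No column of the values was left unused, and among all pairs of arrays none was identical. The genome build is not given in the sources used here, so probe sets carry gene names only. Names came from the array's probe table and a RefSeq gene table of the assembly GRCh38.p14. Of the probe sets, 62 were controls, 41091 had 1 gene symbol, 1801 had several and 11721 were not in the probe table. The gene numbers of 41037 matched the RefSeq table, where 0 symbols needed an update.

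A probe set was kept if it reached a log2 value of 5 on at least 2 arrays, which left 35146 probe sets with 1 symbol. Each gene was represented by its probe set with the highest mean, giving 18055 genes. Array medians lay between 6.46 and 6.58 log2, and 77.1% to 79.1% of probe sets reached 5. RMA had already normalized the arrays, so these values do not measure how alike they were in brightness before it. One model with a mean per group was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 13 residual degrees of freedom, 6.14 prior degrees of freedom). Genes were called at a Benjamini-Hochberg adjusted p under 0.05, 2-sided, in 23 contrasts: each treated group against DMSO, the higher against the lower dose of each compound, and 8 pairs of compounds. Errors of fold changes are SEs from limma, errors of levels are SDs, and intervals are 95% intervals. Per the labels, Aza and G669043 were given at the same doses, while G668684 and DAC, and DAC and Aza, were not. Whether a dose of G669071 matched one of DAC is open. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

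Genes were named by a rule fixed before the values were seen. For the higher dose of each compound against DMSO it takes the 10 raised and 5 lowered called genes with the largest fold changes whose treated arrays both lie beyond all 4 DMSO arrays, and for the lower dose 5 and 3. It adds up to 4 called members of each list with the largest fold changes, DNMT1, DNMT3A, DNMT3B and DNMT3L, and the 3 highest and 3 lowest called genes of the other contrasts. The text names part of this pool. In 437 cases a named gene had more than 1 kept probe set in a comparison, and in 321 of these all went the same way.

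The 25 gene lists were written from general knowledge before the values were seen, with 1031 entries, of which 924 had a probe set. They cover cancer-testis, germ cell, hypermethylated, interferon, antigen presentation, p53, G2/M, S phase, DNA repair, histone, DNA methylation machinery, nucleoside metabolism, esterase, stress response, apoptosis, imprinted, WNT, intestinal, keratinocyte, fibroblast, blood, neuronal, cytokine, cholesterol and ribosome biogenesis genes. The keratinocyte, fibroblast, blood and neuronal lists hold markers of other cell types. Each was tested against DMSO with camera at a preset correlation of 0.01 and again with an estimated correlation, with the adjustment over the lists of a comparison. Their tests in the contrasts of doses and of compounds were chosen after seeing the data. Members were also adjusted over the list alone.

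The model was tested on simulated data in the contrast of Aza at 150 nM with DMSO, with 200 changed genes in each of 20 draws. With noise as in the arrays 73.7%, 98.0% and 99.9% of genes shifted by 0.5, 1 and 2 log2 units were called, with a median of 1 and at most 6 unchanged genes called. With independent noise these shares were 72.0%, 98.1% and 99.9%, with a median of 11.5 and at most 19 unchanged genes called. A p53 list shifted by 0.3 was called in 20 of 20 draws with either noise. Among the other lists, a median of 1 and up to 8 were called with the preset and 0 with the estimated correlation under noise as in the arrays, and a median of 0, up to 2 and up to 1 under independent noise. Noise was drawn separately for each array, so false calls from arrays of a group that deviate together are not counted. This test was made after the main fit.

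The alternatives were no filter on dim probe sets, a filter at a log2 value of 6, the mean of a gene's probe sets, no probe sets that can bind several transcripts, no intensity trend, a fit of the compared arrays alone, quantile normalization again, centring on array medians, a replicate block, array weights, an estimated correlation, split controls, and each array left out in turn. After seeing the data, DMSO replicates 1 and 2 alone, DMSO replicates 3 and 4 alone, and the beta-actin 3 prime minus 5 prime value as a covariate were added. Relations with array quality were tested by exact permutation within groups, 2-sided, over 24576 arrangements, since the deviations of 2 arrays from their mean mirror each other. For comparisons that share DMSO, chance correlations and overlaps came from 100 simulations of unchanged groups each. Their noise was drawn separately for each array, so arrays of a simulated group did not deviate together. The simulated overlaps are those of the highest ranked genes of each direction, in lists of the observed sizes. Overlaps with separate DMSO arrays for each comparison are means over the 6 splits of DMSO, added after seeing the data like the simulated overlaps. The control probe sets and those without a gene name were left out of the counts of genes.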

Results

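HCT116 cells, an established human colorectal cancer line, were treated for 72 h with inhibitors of DNA methyltransferase 1 or with the solvent dimethyl sulfoxide (DMSO), and their RNA was hybridized to Affymetrix HG-U133 Plus 2.0 arrays. Decitabine (DAC) and azacytidine (Aza) are cytidine analogues that trap DNA methyltransferases on newly replicated DNA, and both were set beside compounds named in the labels only as the prodrugs G669071, G668684 and G669043. The titles of the G669043 samples begin with the short name of Aza, while their source names give the prodrug alone. How the compound relates to Aza is not settled here. The 24 arrays formed 11 groups, with 4 arrays for DMSO and 2 for each compound and dose. DAC was given at 5 µM and 120 nM, G668684 at 7 µM and 150 nM, and Aza and G669043 each at 1500 nM and 150 nM. The doses of G669071 were 63 µM and 6 µM in the sample titles, while the source names of the same samples stated 120 nM and 6 nM. Its groups are called the higher and the lower dose here, and what was given at each is not settled. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision: the median 95% interval of a log2 fold change reached 0.21 to each side against DMSO and 0.24 between treated groups. The values are fold changes of 18055 genes on the log2 scale with their standard error (SE) from limma, and the probe sets are not placed on a genome because a build was not given in the sources used here.

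Replicate arrays of a treated group correlated at 0.990 to 0.998 across the tested genes. The DMSO arrays formed separate pairs: replicates 1 and 2 correlated at 0.997, replicates 3 and 4 at 0.997, and arrays of different pairs at 0.990 to 0.991. Such a split was not limited to DMSO, since the 2 arrays of DAC at 120 nM correlated at 0.990. The beta-actin 3 prime minus 5 prime value, a sign of RNA quality, was -0.03 and 0.00 log2 in DMSO replicates 1 and 2 and 0.24 and 0.15 in replicates 3 and 4. The same value for GAPDH was -0.14, -0.16, -0.15 and -0.17 in DMSO replicates 1, 2, 3 and 4, and it did not part the pairs. Of the variance across arrays, the first 3 principal components held 53.4%, 15.8% and 7.52%. Against DMSO, between 157 and 5809 of the 18055 genes were called at an adjusted p under 0.05.

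**Figure D1:**
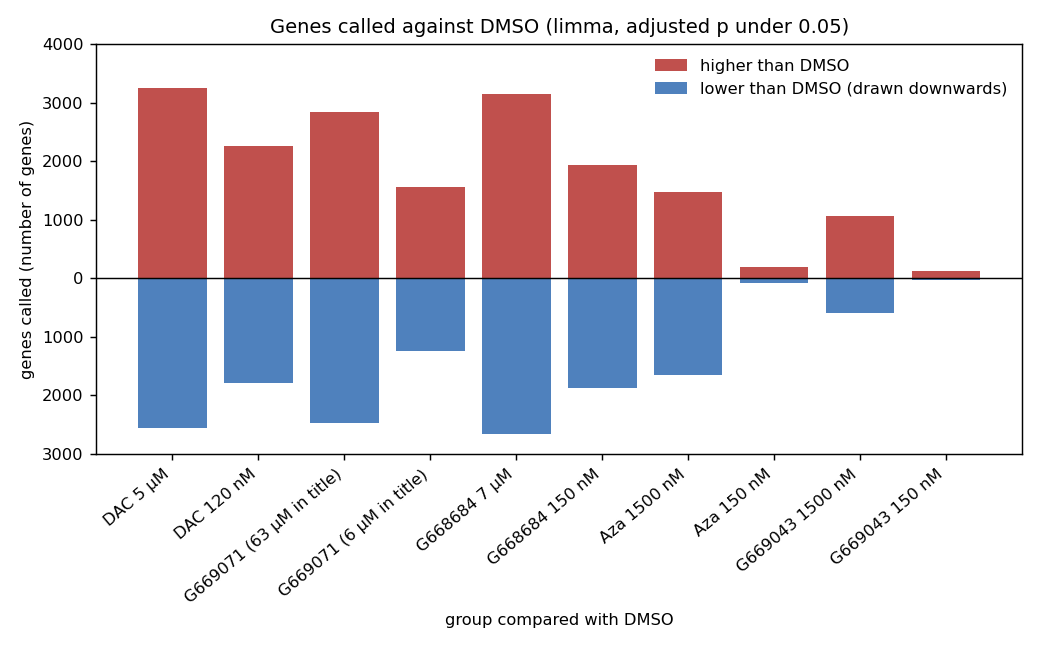
Number of genes called against DMSO (y axis, genes; upwards for higher, downwards for lower) in each of the 10 treated groups (x axis), by limma at an adjusted p under 0.05. DAC at 5 µM and G668684 at 7 µM had 5806 and 5809 called genes, and G669043 at 150 nM had 157.

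With DAC at 5 µM, genes of the germ line and testis rose most. TKTL1, a transketolase-like gene, rose by 7.01 ± 0.16 (log2 fold change ± SE, 2 arrays against 4, adjusted p = 5.4e-17) from a DMSO level of 5.24 ± 0.37 (SD, n = 4). DAZL, an RNA-binding protein of germ cells, rose by 6.76 ± 0.19, GCNA by 5.68 ± 0.15, the cancer-testis antigen MAGEA4 by 5.46 ± 0.16 and MAEL, which acts against transposons in the germ line, by 5.20 ± 0.11. The neuropeptide precursor TAC1 rose by 4.30 ± 0.16, and CDO1, a cysteine dioxygenase, by 4.30 ± 0.15, although only 1 of its 2 probe sets went that way. The DMSO levels of DAZL, at 4.23 ± 0.21, and TAC1, at 3.67 ± 0.17 (SD, n = 4), lay under the filter value of 5 and near the lowest of all tested genes, at percentiles 0.144 and 0.0443. Whether these levels lay above background is unknown, so the folds of both genes against DMSO here and in the other groups have a size that is not settled and may be understated. The largest falls were in the mitotic genes CENPF, at -2.02 ± 0.29, and KIF15, at -1.97 ± 0.16, in the protocadherin PCDH7, at -1.83 ± 0.13, and in the helicase gene BRIP1, at -1.75 ± 0.13. Only 2 of the 5 probe sets of PCDH7 went down, and the mean of its probe sets gave 0.15 in place of a fall. In all, 3251 genes were higher and 2555 lower, of which 465 and 110 changed at least 2-fold. At 120 nM, TKTL1 rose by 7.70 ± 0.16, GCNA by 6.34 ± 0.15 and DAZL by 6.25 ± 0.19, while HS3ST1, a heparan sulfate sulfotransferase, was lower at -2.16 ± 0.18 (2 of 3 probe sets) and the annexin ANXA10 at -2.05 ± 0.07. That dose gave 2252 higher and 1787 lower genes, or 1504 and 1526 without probe sets that can bind several transcripts.

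Among the gene groups that moved with DAC were those of the germ line, p53, DNA replication and histones. Of 29 cancer-testis genes tested, 23 rose and 1 fell at 5 µM (23 and 1 adjusted over the list alone) and 22 rose and 1 fell at 120 nM (22 and 1 adjusted over the list alone), with list medians of 1.16 and 1.74. Of 30 germ cell and meiosis genes, 21 rose at 5 µM and 20 at 120 nM (24 and 23 adjusted over the list alone), and 1 fell at each dose. Among 55 p53 target genes, 40 rose and 1 fell at 5 µM (42 and 1 adjusted over the list alone), led by TP53I3 at 2.64 ± 0.09 and TIGAR at 2.12 ± 0.14. At 120 nM, 26 of them rose and 2 fell (26 and 2 adjusted over the list alone). Of 51 genes of S phase and DNA replication, 49 fell at 5 µM and 33 at 120 nM (49 and 37 adjusted over the list alone), among them PRIM1, a DNA primase subunit, at -1.32 ± 0.06 and -0.68 ± 0.06. Of 59 genes of G2/M and mitosis, 50 fell at 5 µM and 14 at 120 nM (52 and 14 adjusted over the list alone), and the call at 120 nM had an adjusted p = 0.43 with an estimated correlation and was lost without replicate 1 of that group (adjusted p = 0.087). Of 19 polyadenylated and linker histone genes, 12 rose at each dose (12 and 12 adjusted over the list alone), with H2BC5 at 3.17 ± 0.09 and H2BC12 at 2.74 ± 0.13 at 5 µM, and 4 fell at 5 µM.

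Transcripts of the DNA methyltransferases themselves moved less. DNMT1, the maintenance methyltransferase, fell at 5 µM DAC, at -0.63 ± 0.09 (adjusted p = 1.9e-05), and was at -0.04 ± 0.09 at 120 nM, which was not called. DNMT3B, a de novo methyltransferase, was lower at 5 µM at -0.57 ± 0.15 (adjusted p = 0.0046, and 0.28 without replicate 2 of that group). DNMT1 was also lower with the higher doses of G668684, at -0.60 ± 0.09, and of G669071, at -0.33 ± 0.09, the latter with an adjusted p = 0.0093, or 0.11 without its replicate 1. DNMT3B was called with G668684 at 7 µM, at -0.48 ± 0.15 (adjusted p = 0.016), and that call was lost without either treated array (adjusted p = 0.12 without replicate 1 and 0.063 without replicate 2). DNMT1 and DNMT3B were not called in any of the other groups against DMSO, and DNMT3A and DNMT3L were not called in any of the 10. DNMT3A passed when single arrays were left out: with DAC at 120 nM without DMSO replicate 1 (adjusted p = 0.046) or replicate 2 of DAC (0.024), and with G668684 at 7 µM without its replicate 2 (0.045). Against DMSO replicates 1 and 2 alone, DNMT3B was called higher with G669043 at 150 nM, at 0.52 (adjusted p = 0.017).

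**Figure D2:**
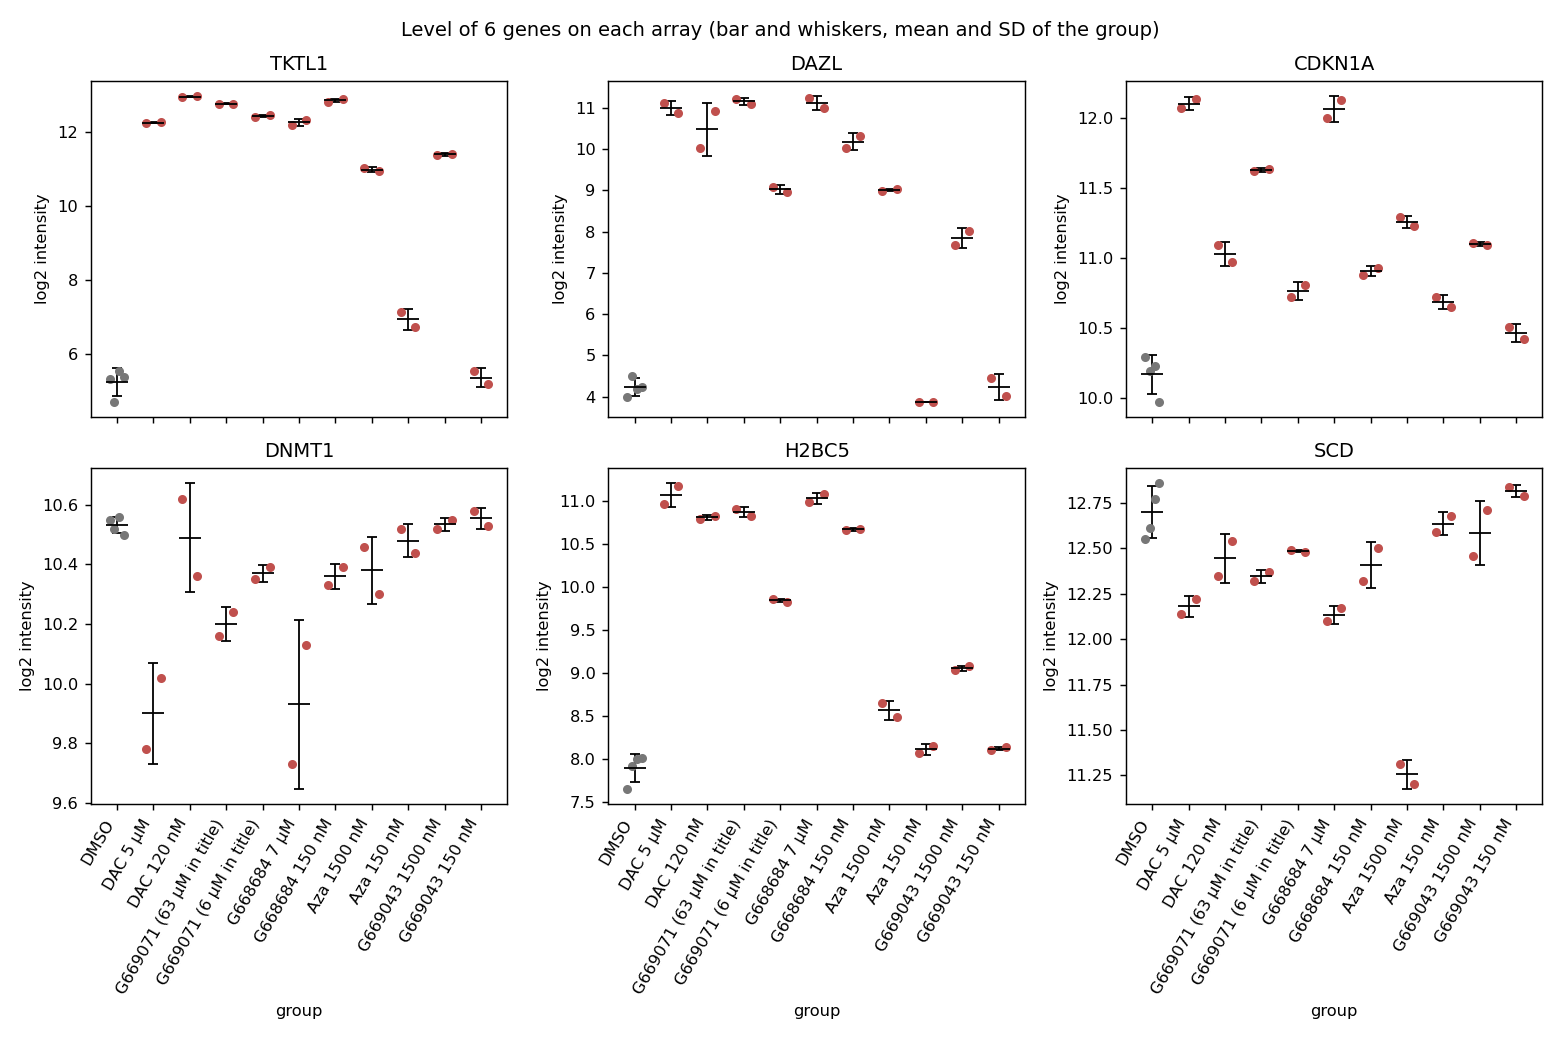
Level of 6 genes on each array (y axes, log2 intensity; points, arrays; bars and whiskers, mean and SD of the group) in DMSO (4 arrays) and in the treated groups (2 arrays each, x axis). TKTL1 lay at 5.24 in DMSO, rose by 7.01 with DAC at 5 µM and by 1.69 with Aza at 150 nM, while SCD was lowest with Aza at 1500 nM.

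With G669071 at its higher dose TKTL1 rose by 7.52 ± 0.16, DAZL by 6.92 ± 0.19, GCNA by 6.30 ± 0.15 and the RNA-binding gene LIN28B by 4.95 ± 0.14, while HS3ST1 was lower at -1.86 ± 0.18. PCDH7 was called lower at -1.60 ± 0.13, but 3 of its 5 probe sets went up and their mean gave 0.67. Of the lists, 22 of 29 cancer-testis genes rose and 1 fell (23 and 1 adjusted over the list alone), 37 of 55 p53 targets rose and 1 fell (39 and 1 adjusted over the list alone), and 45 of 51 S phase genes fell (47 adjusted over the list alone). At the lower dose TKTL1 rose by 7.19 ± 0.16 and DAZL by 4.79 ± 0.19, 21 of 29 cancer-testis genes rose (23 adjusted over the list alone) and 27 of 51 S phase genes fell (31 adjusted over the list alone). The p53 targets, with 20 higher and 1 lower (23 and 2 adjusted over the list alone), had an adjusted p = 0.098 with an estimated correlation. The higher dose called 2846 genes higher and 2476 lower (1953 and 2012 without probe sets that can bind several transcripts), and the lower dose 1567 and 1248. The total of 2815 at the lower dose was 1455 without its replicate 1 and 1309 without its replicate 2.

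With G668684 at 7 µM, TKTL1 rose by 7.02 ± 0.16, DAZL by 6.88 ± 0.19 and the cell cycle inhibitor CDKN1A by 1.90 ± 0.07, and KIF15 was lower at -2.08 ± 0.16 and CENPF at -1.95 ± 0.29. The level of CENPF was 7.865 ± 1.15 (SD, n = 2), so the size of its fall differed widely between the 2 arrays. PCDH7 was called lower at -1.86 ± 0.13 with 2 of its 5 probe sets, and the mean of its probe sets gave 0.12. Of 29 cancer-testis genes 24 rose and 1 fell (24 and 1 adjusted over the list alone), of 55 p53 targets 38 rose and 2 fell (40 and 2 adjusted over the list alone), and of 51 S phase genes 48 fell (49 adjusted over the list alone). At 150 nM, TKTL1 rose by 7.61 ± 0.16 and GCNA by 6.20 ± 0.15, HS3ST1 was lower at -2.07 ± 0.18 (2 of 3 probe sets) and ANXA10 at -1.83 ± 0.07. PCDH7 was called lower at -1.89 ± 0.13 there, and the mean of its probe sets gave 0.15. At that dose 23 cancer-testis genes rose (23 higher and 1 lower adjusted over the list alone) and 34 S phase genes fell (38 adjusted over the list alone). The higher dose called 3153 genes higher and 2656 lower, and the lower dose 1926 and 1876, a total of 3802 that was 2239 without its replicate 1. Lower genes outnumbered higher ones at the lower dose under 8 alternatives, with 1304 higher and 1483 lower without its replicate 2 and 1884 and 2139 without DMSO replicate 1.

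Aza at 1500 nM raised germ line genes and lowered genes of cholesterol and fatty acid synthesis. Of 29 cancer-testis genes 18 rose and 0 fell (18 and 0 adjusted over the list alone), and of 30 germ cell and meiosis genes 12 rose and 0 fell (14 and 0 adjusted over the list alone; adjusted p = 1.8e-04 and 0.0031 with an estimated correlation). TKTL1 rose by 5.74 ± 0.16, DAZL by 4.78 ± 0.19, MAGEA4 by 4.04 ± 0.16 and the intermediate filament gene VIM by 2.71 ± 0.07. The largest fall by the chosen probe set was in PCDH7, at -2.31 ± 0.13, where 3 of 5 probe sets went the other way, followed by the nuclear receptor NR2F1 at -1.82 ± 0.19 and S100A4 at -1.78 ± 0.07. Of 24 genes of cholesterol and fatty acid synthesis, 15 fell and 0 rose (15 and 0 adjusted over the list alone; list median -0.29, adjusted p = 0.0053 with an estimated correlation). Among them SCD, the stearoyl-CoA desaturase, was at -1.44 ± 0.08, STARD4 at -0.84 ± 0.08 and INSIG1 at -0.81 ± 0.16 (adjusted p = 0.058 without replicate 2 of the group). In the unfolded protein and integrated stress response list, 12 of 35 genes fell and 4 rose (13 and 5 adjusted over the list alone), with SLC7A11 at -0.97 ± 0.09 and ATF4 at -0.96 ± 0.08 (list adjusted p = 0.46 with an estimated correlation). Of 55 p53 targets 27 rose and 1 fell (32 and 1 adjusted over the list alone). Of 51 S phase genes 4 rose and 6 fell (4 and 7 adjusted over the list alone), and that list was not called (median -0.03). There were 1467 higher and 1658 lower genes, and the total of 3125 was 1960 without replicate 1 and 1643 without replicate 2 of the group. Higher genes outnumbered lower ones without replicate 2 (971 and 672), without DMSO replicate 3 (1443 and 1340), against DMSO replicates 1 and 2 alone (1552 and 1156) and with the beta-actin value as a covariate (1779 and 1704).

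At 150 nM, Aza changed few genes. SRGN, which encodes a proteoglycan core protein, rose by 1.73 ± 0.23 from a DMSO level of 4.34 ± 0.58 (SD, n = 4) under the filter value, TKTL1 by 1.69 ± 0.16, DHRS2 by 1.61 ± 0.10 and VIM by 1.08 ± 0.07, and ANXA10 fell, at -0.84 ± 0.07. Of 55 p53 targets 8 rose (14 higher and 1 lower adjusted over the list alone; list adjusted p = 0.2 with an estimated correlation), with CDKN1A at 0.52 ± 0.07. In all 186 genes were higher and 83 lower. The split was 182 and 155 with arrays normalized to the same quantiles again, and 128 and 32 with arrays centred on their medians. The total of 269 became 56 without replicate 1 and 63 without replicate 2 of the group, and was 547 against DMSO replicates 1 and 2 alone and 1270 against replicates 3 and 4 alone, controls chosen after seeing the data.

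With G669043 at 1500 nM, TKTL1 rose by 6.15 ± 0.16, GCNA by 5.23 ± 0.15, MAGEA4 by 4.88 ± 0.16, SRGN by 3.16 ± 0.23 and DHRS2 by 2.82 ± 0.10. ANXA10 was lower at -1.37 ± 0.07, and PCDH7 was called at -1.56 ± 0.13 with 2 of 5 probe sets going that way (adjusted p = 0.058 for the mean of its probe sets). Of 29 cancer-testis genes 16 rose (18 adjusted over the list alone), and of 55 p53 targets 22 rose and 1 fell (29 and 4 adjusted over the list alone). Of 24 cholesterol and fatty acid synthesis genes 3 rose and 1 fell (4 and 2 adjusted over the list alone), and the list was not called (median 0.09), although it was called higher without DMSO replicate 3 or 4 (adjusted p = 0.031 and 0.031) or replicate 1 of the group (0.0082). Of 19 histone genes 5 rose (5 adjusted over the list alone), with H2BC12 at 1.32 ± 0.13 (list adjusted p = 0.061 with an estimated correlation). There were 1061 higher and 586 lower genes, or 980 and 312 with arrays centred on their medians and 1115 and 1066 with the beta-actin value as a covariate. The total of 1647 was 856 without replicate 1 and 576 without replicate 2 of the group, 2788 against DMSO replicates 1 and 2 alone and 2501 against replicates 3 and 4 alone.

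At 150 nM, G669043 gave 128 higher and 29 lower genes, none of them changed 2-fold, and 3425 genes at an unadjusted p under 0.05. SUN3 was called higher at 0.92 ± 0.14, SLC2A3, a glucose transporter, at 0.78 ± 0.11 and TNNC1 at 0.70 ± 0.08, and the stress cytokine GDF15 at 0.58 ± 0.09, with 2 of its 3 probe sets (-0.04 without probe sets that can bind several transcripts). Leaving out either treated array ended the calls of SUN3 (adjusted p = 0.16 and 0.052) and GDF15 (0.16 and 0.12), that of SLC2A3 was lost without replicate 2 (0.22), and that of TNNC1 was kept under each array left out. TKTL1, DAZL, GCNA, MAGEA4 and MAEL, called in the 6 groups given DAC, G669071 or G668684, were not called here. Of the lists 13 were called, 10 higher and 3 lower, and with an estimated correlation 0 were, while 1 was called with arrays normalized to the same quantiles again. Quantile normalization also changed the split of called genes to 27 higher and 19 lower, and the beta-actin covariate to 868 and 356. The total of 157 was 49 without DMSO replicate 1, 961 without DMSO replicate 3, 7 without replicate 1 and 3 without replicate 2 of the group, and 5084 against DMSO replicates 1 and 2 alone. Against DMSO replicates 3 and 4 alone the total stayed within the set bounds for counts, described below. On principal component 2 the arrays of the group lay at 16.5 and 14.1. DMSO replicates 3 and 4 lay at 18.2 and 12.8 there, and DMSO replicates 1 and 2 at -13.6 and -11.1. The 5084 thus came with the DMSO pair that lay farther from the group on this component. The total of 157 was 0 by limma in a fit of this group and DMSO alone, with 1573 at an unadjusted p under 0.05.

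**Figure D3:**
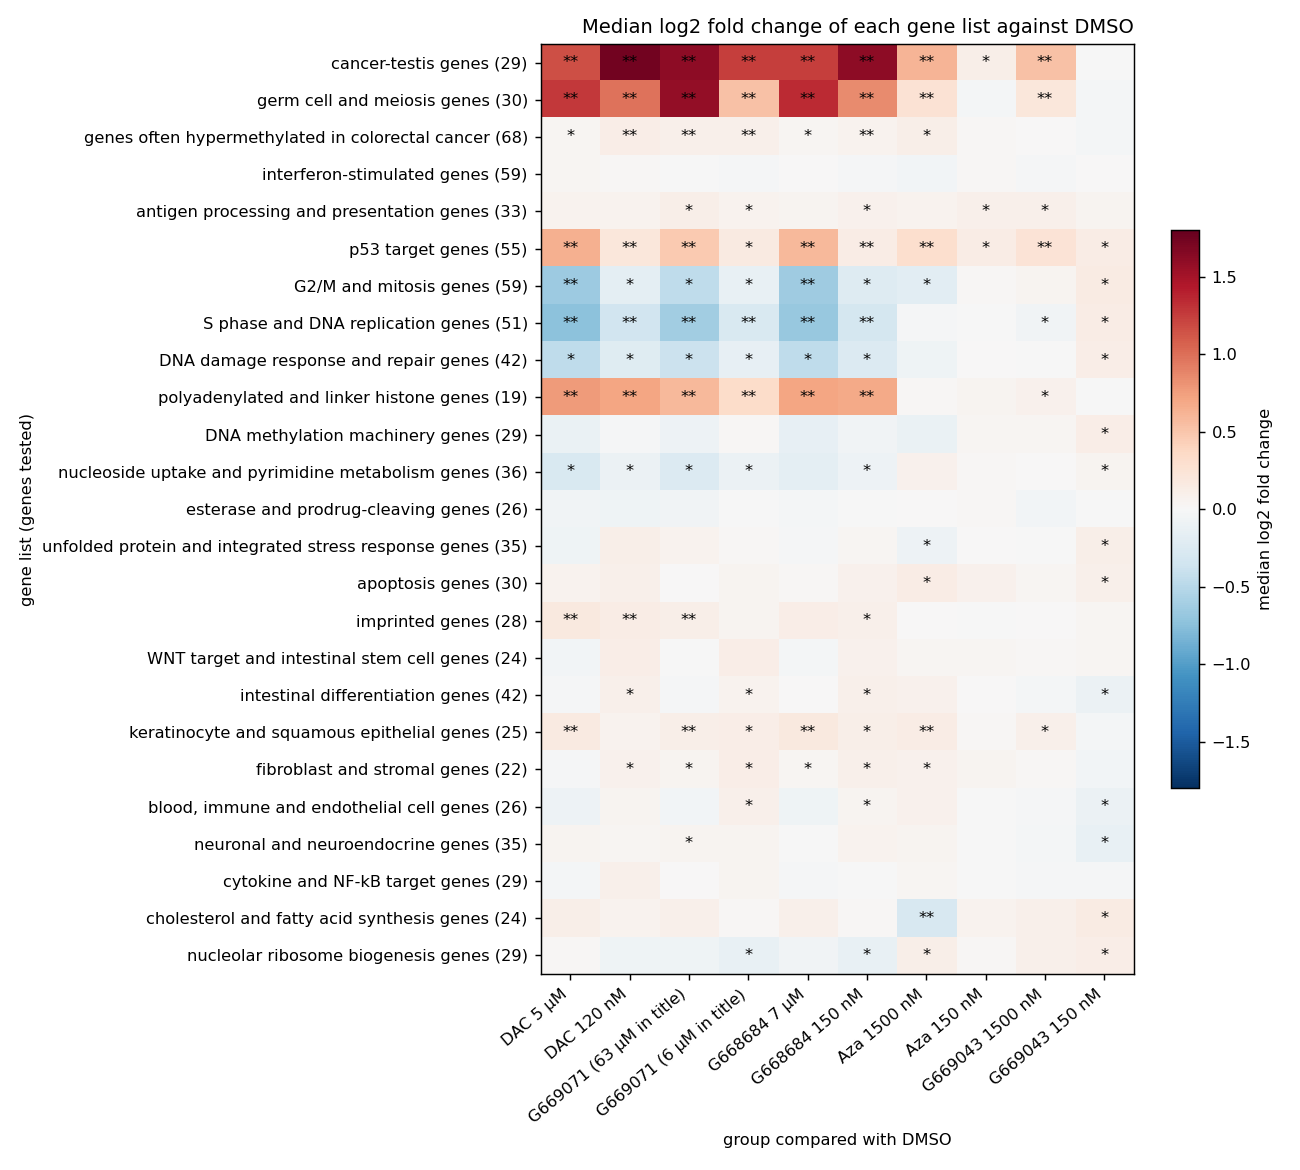
Median log2 fold change against DMSO (colour, log2 scale) of 25 gene lists (y axis, number of genes tested in parentheses) in the 10 treated groups (x axis). A single asterisk marks a call by camera with a preset correlation and a double asterisk a call that also held with an estimated correlation. Cancer-testis genes reached a median of 1.74 with DAC at 120 nM, and cholesterol and fatty acid synthesis genes were at -0.29 with Aza at 1500 nM.

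The 25 lists were tested with camera at a preset correlation of 0.01 between genes. With an estimated correlation the following calls against DMSO held. Cancer-testis and germ cell genes were higher in the 6 groups given DAC, G669071 or G668684 and with Aza and G669043 at 1500 nM. The p53 targets were higher in those 8 groups apart from the lower dose of G669071. S phase genes were lower and histone genes higher in the 6 groups given DAC, G669071 or G668684. G2/M genes were lower with DAC at 5 µM and G668684 at 7 µM, and genes often hypermethylated in colorectal cancer were higher with DAC at 120 nM, both doses of G669071 and G668684 at 150 nM. Imprinted genes were higher with both doses of DAC and the higher dose of G669071, keratinocyte genes at the higher doses of DAC, G669071, G668684 and Aza, and cholesterol genes lower with Aza at 1500 nM. The number of lists called by the preset and held by the estimate was 11 and 8 for DAC at 5 µM, 12 and 7 at 120 nM, 14 and 8, and 15 and 5, for the higher and lower dose of G669071, 10 and 7, and 16 and 6, for G668684, 11 and 5, and 3 and 0, for Aza, and 7 and 3 for G669043 at 1500 nM.

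Among the 68 genes often hypermethylated in colorectal cancer, 24 rose and 4 fell with DAC at 5 µM (24 and 4 adjusted over the list alone), where the list was called with a median of 0.03 and a mean of 0.55 and had an adjusted p = 0.058 with an estimated correlation. The matricellular gene SPARC rose by 3.56 ± 0.21 and VIM, also on the fibroblast list, by 3.21 ± 0.07. UCHL1 rose by 3.96 ± 0.15 by 1 of its 2 probe sets, and without probe sets that can bind several transcripts it was at -0.06. This list was also called with G668684 at 7 µM (adjusted p = 0.06 with an estimated correlation) and with Aza at 1500 nM (0.23). Of 28 imprinted genes 11 rose and 2 fell with DAC at 5 µM (12 and 2 adjusted over the list alone), led by NAP1L5 at 1.49 ± 0.12. Imprinted genes were also called with G668684 at 150 nM (adjusted p = 0.062 with an estimated correlation), a call lost without DMSO replicate 2 (0.053) or replicate 2 of the group (0.050). Of 42 DNA repair genes 25 fell and 1 rose with DAC at 5 µM (28 and 1 adjusted over the list alone). That list was called lower in the 6 groups given DAC, G669071 or G668684, with adjusted p = 0.091 to 0.39 with an estimated correlation. Of 42 intestinal differentiation genes 6 rose and 1 fell with DAC at 5 µM, which was not called (6 and 1 adjusted over the list alone), although KRT20, a keratin of differentiated colon epithelium, rose by 3.01 ± 0.10.

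Other lists were called by the preset alone in part of the comparisons. Keratinocyte genes were called higher at the lower doses of G669071 and G668684 and with G669043 at 1500 nM (adjusted p = 0.19, 0.12 and 0.12 with an estimated correlation). Each of these calls was lost without 1 array: DMSO replicate 3 (adjusted p = 0.084) or replicate 1 of the group (0.060), replicate 1 of the group (0.052), and DMSO replicate 3 (0.059). Fibroblast genes were called higher with DAC at 120 nM, with both doses of G669071 and of G668684 and with Aza at 1500 nM (adjusted p = 0.12 to 0.37 with an estimated correlation), where at most 5 of 22 rose. That call was lost for G668684 at 7 µM without DMSO replicate 3 (adjusted p = 0.071) or its replicate 1 (0.054), and for Aza without its replicate 2 (0.084). Antigen presentation genes were called higher with both doses of G669071, G668684 at 150 nM, Aza at 150 nM and G669043 at 1500 nM (adjusted p = 0.34 to 0.67 with an estimated correlation). They were no longer called without DMSO replicate 3 (adjusted p = 0.054) or replicate 2 of the group (0.078) for the higher dose of G669071, and without replicate 1 of the group for G668684 (0.11), Aza (0.20) and G669043 (0.17). Cancer-testis genes were called with Aza at 150 nM, where 1 of 29 rose (3 adjusted over the list alone), with an adjusted p = 0.22 with an estimated correlation, or 0.11 by the preset without replicate 1 of the group.

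Lists of metabolism and growth moved with calls of the same kind. Nucleoside uptake and pyrimidine metabolism genes were called lower with DAC at both doses, with G669071 at both doses and with G668684 at 150 nM (adjusted p = 0.055 to 0.13 with an estimated correlation), while the uridine phosphorylase UPP1 rose by 1.87 ± 0.11 with DAC at 5 µM. Without DMSO replicate 3 the call for DAC at 5 µM was lost (adjusted p = 0.053), without replicate 1 of the group those for DAC at 120 nM (0.061) and G668684 (0.10), and the latter also without DMSO replicate 2 (0.053). Nucleolar ribosome biogenesis genes were called lower at the lower doses of G669071 and G668684 and higher with Aza at 1500 nM, and apoptosis genes higher with the latter (adjusted p = 0.34 to 0.51 with an estimated correlation). Both calls with Aza were lost without DMSO replicate 1 (adjusted p = 0.056 and 0.069) or replicate 1 of the group (0.10 and 0.10). G2/M genes were called lower with both doses of G669071, with G668684 at 150 nM and with Aza at 1500 nM (adjusted p = 0.11 to 0.52 with an estimated correlation). S phase genes were called lower with G669043 at 1500 nM (adjusted p = 0.60 with an estimated correlation), a call lost without DMSO replicate 3 (0.22), DMSO replicate 4 (0.065) or replicate 1 of the group (0.23).

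Calls of the remaining tissue lists held with the preset only. Intestinal differentiation genes were called higher with DAC at 120 nM, the lower dose of G669071 and G668684 at 150 nM (adjusted p = 0.36 to 0.52 with an estimated correlation). Those calls were lost without replicate 1 of DAC (adjusted p = 0.29), DMSO replicate 3 (0.15) or 4 (0.076), and replicate 1 of G668684 (0.086). Blood and immune genes were called higher at the lower doses of G669071 and G668684 (adjusted p = 0.47 and 0.47 with an estimated correlation), and neither was called without DMSO replicate 3 (0.073 and 0.090), nor the second without its replicate 1 (0.11). Neuronal genes were called higher with the higher dose of G669071 (adjusted p = 0.23 with an estimated correlation), a call lost without DMSO replicate 3 (0.093) or replicate 1 of the group (0.088). Interferon-stimulated genes (59 tested), WNT targets (24), cytokine genes (29) and esterase genes (26) were called in 0 of the 10 comparisons by camera with either correlation. At 5 µM DAC, 12 interferon-stimulated genes rose and 14 fell (13 and 14 adjusted over the list alone), IRF7 rising by 2.10 ± 0.14. Without DMSO replicate 3 or 4 the interferon-stimulated list was called lower with Aza at 1500 nM (adjusted p = 0.049 and 0.024), and without replicate 2 of the group the cytokine list was called higher with the higher dose of G669071 (0.0062).

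With G669043 at 150 nM the lists called higher were p53 targets, G2/M, S phase, DNA repair, DNA methylation machinery, nucleoside metabolism, unfolded protein response, apoptosis, cholesterol and ribosome biogenesis genes, and those called lower were intestinal differentiation, blood and neuronal genes (adjusted p = 0.24 to 0.55 with an estimated correlation). Without replicate 1 of the group, DNA repair (adjusted p = 0.080), unfolded protein response (0.17), apoptosis (0.080), intestinal differentiation (0.38) and blood genes (0.14) were not called, and without its replicate 2 nucleoside genes were not (0.20). Without DMSO replicate 1 the nucleoside (0.054), intestinal (0.088) and blood genes (0.054) were not called, without DMSO replicate 2 the intestinal genes (0.051), and without DMSO replicate 4 the nucleoside genes (0.055).

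In 36 of the 250 tests of a list against DMSO the median, the mean and the test did not share a sign, and none of these was called. With DAC at 5 µM the median was negative and the test upward for esterase, WNT, intestinal, fibroblast, blood and cytokine genes, as for fibroblast genes with a median of -0.03 and a mean of 0.49, and ribosome genes had the opposite. The fibroblast list was called there without DMSO replicate 1 (adjusted p = 0.025), DMSO replicate 2 (0.047) or DAC replicate 2 (0.029). The same disagreement was met with DAC at 120 nM for DNA methylation machinery genes, and with the higher dose of G669071 for interferon-stimulated, unfolded protein response, WNT, intestinal and blood genes. It was met at the lower dose of G669071 and with G668684 at 150 nM for interferon-stimulated and cholesterol genes, in the latter also for cytokine genes, and with G668684 at 7 µM for esterase, WNT, blood, neuronal and cytokine genes. With Aza it concerned esterase and imprinted genes at 1500 nM and germ cell, esterase, unfolded protein response, blood and cytokine genes at 150 nM. With G669043 it concerned interferon-stimulated, intestinal, blood and cytokine genes at 1500 nM and interferon-stimulated and imprinted genes at 150 nM.

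Between doses, TAC1 was higher at the higher dose of DAC, G669071 and G668684 by 3.33 ± 0.18, 3.62 ± 0.18 and 3.19 ± 0.18, but its levels at the lower doses, 4.65, 4.23 and 4.82, lay under the filter value of 5, so the sizes are not settled. The potassium channel gene KCNV2 was higher by 2.12 ± 0.19, 2.93 ± 0.19 and 2.50 ± 0.19. CENPF was lower at the higher dose of DAC at -1.99 ± 0.33 and of G668684 at -1.39 ± 0.33, the latter with an adjusted p = 0.0081, or 0.22 without G668684 7 µM replicate 1 and 0.11 without 150 nM replicate 1. For these contrasts the lists were tested after seeing the data. The p53 targets were higher and S phase genes lower at the higher dose of each of these compounds, with medians of 0.33 and -0.38 for DAC, with 28 of 55 higher and 30 of 51 lower (33 higher and 34 lower adjusted over the list alone; adjusted p = 0.0075 and 0.016 with an estimated correlation). For Aza, DAZL was higher at 1500 nM by 5.14 ± 0.22, from a level of 3.87 under the filter value, and S100A4 lower at -1.64 ± 0.08, and the cholesterol list was lower by a median of -0.39 (adjusted p = 4.6e-04 with an estimated correlation). For G669043, TKTL1 was higher at 1500 nM by 6.03 ± 0.18 and ANXA10 lower at -1.16 ± 0.08. The genes called higher and lower at the higher dose were 1577 and 1073 for DAC, 1020 and 669 for G669071, 1405 and 681 for G668684, 435 and 610 for Aza, and 306 and 393 for G669043. Normalized to the same quantiles again, G668684 gave 1308 and 1075 and G669043 gave 382 and 255, and with the beta-actin covariate G669043 gave 907 and 1863.

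Leaving out 1 array moved these dose counts. The 2650 genes for DAC became 1590 and 1444 without replicates 1 and 2 at 5 µM and 1598 without replicate 1 at 120 nM. The 1689 for G669071 became 877 and 876 without replicates 1 and 2 at the higher dose and 890 and 725 at the lower. The 2086 for G668684 became 1245 without replicate 1 at 7 µM and 1049 without replicate 1 at 150 nM. The 1045 for Aza became 633 and 345 at 1500 nM and 368 and 339 at 150 nM, and the 699 for G669043 became 230 and 248 at 1500 nM and 256 and 241 at 150 nM. For Aza the excess of lower genes turned without replicate 2 at 1500 nM (203 higher and 142 lower) or at 150 nM (177 and 162). For G669043 it turned without any of the 4 arrays, with 136 and 94 or 125 and 123 without replicates 1 and 2 at 1500 nM, and 162 and 94 or 121 and 120 at 150 nM.

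Aza and G669043 were given at the same doses, which allowed a direct comparison. At 1500 nM, G669043 gave higher levels of SUSD2, by 1.36 ± 0.16, and of SCD, by 1.33 ± 0.10 (adjusted p = 3.3e-07), and lower levels of the lipocalin LCN2, at -1.35 ± 0.10, of DAZL, at -1.17 ± 0.22, and of the carbonyl reductase CBR1, at -1.15 ± 0.13. Of 24 cholesterol and fatty acid synthesis genes, 15 were higher with G669043 than with Aza and 0 lower (20 and 0 adjusted over the list alone), with a median difference of 0.44 (adjusted p = 3.4e-04 with an estimated correlation). In total 265 genes were higher and 119 lower, or 178 and 37 with arrays centred on their medians. With the beta-actin value as a covariate, chosen after seeing the data, 119 were higher and 129 lower. The mean of that value was 0.20 in G669043 (arrays at 0.07 and 0.34) and 0.02 in Aza (log2, n = 2 each). The total of 384 was 172 and 65 without replicates 1 and 2 of Aza, and 197 and 47 without replicates 1 and 2 of G669043. The call of DAZL was lost without Aza replicate 2 (adjusted p = 0.10) and without G669043 replicate 1 (adjusted p = 0.073). At 150 nM, 2 genes were higher with G669043, DDIT4 by 0.82 ± 0.13 and ANXA10 by 0.63 ± 0.08, and 10 lower, among them TKTL1 at -1.57 ± 0.18 and DHRS2 at -1.29 ± 0.11. The total of 12 was 6 and 5 without replicates 1 and 2 of Aza. A fit of the compared arrays alone called 985 higher and 215 lower at 1500 nM and 1505 and 341 at 150 nM. Array weights gave 880 and 385, and 319 and 302. The excess of lower genes at 150 nM turned under both. The call of DDIT4 was lost without replicate 1 or 2 of Aza (adjusted p = 0.16 and 0.18) or replicate 1 of G669043 (0.19).

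G668684 was given at doses unlike those of DAC, and the doses of G669071 are not settled, so the values stand side by side. G668684 at 7 µM and DAC at 5 µM differed in 0 genes by limma at an adjusted p under 0.05, with 192 at an unadjusted p under 0.05. TKTL1 rose by 7.02 and 7.01, DAZL by 6.88 and 6.76, and the largest differences of any gene were 0.57 and -0.63. The 95% interval of the difference lay within 1 log2 unit for 99.98% of genes. At 150 nM G668684 and 120 nM DAC, limma called 0 genes, with 593 at an unadjusted p under 0.05 and 4 called with the beta-actin value as a covariate. The differences lay between -0.67 and 0.48, and the interval within 1 log2 unit for 99.9% of genes. G669071 at the higher dose differed from DAC at 5 µM in 163 genes, 37 higher and 126 lower (90 and 181 with the beta-actin covariate), with RCAN2 at -1.06 ± 0.12 and the p53 list lower by a median of -0.15 (adjusted p = 0.0086 with an estimated correlation), while the cancer-testis list was higher by 0.27 (0.0055) with 0 of its 29 genes called (2 adjusted over the list alone). The total of 163 was 42 and 16 without replicates 1 and 2 of DAC, and 22 and 45 without replicates 1 and 2 of G669071. At the lower doses 13 genes were higher and 88 lower with G669071 than with DAC, led by DPY19L2P2 at -1.69 ± 0.18, and the cancer-testis list was lower by a median of -0.33 (adjusted p = 7.2e-04 with an estimated correlation). The total of 101 was 41 without DAC replicate 1 and 20 and 13 without replicates 1 and 2 of G669071, and 0 by limma in a fit of these arrays alone, with 1138 at an unadjusted p under 0.05.

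DAC and Aza, also at unlike doses, differed in S phase, histone and lipid genes. With DAC at 5 µM, CLIC3 was higher than with Aza at 1500 nM by 3.42 ± 0.14, and the amino acid synthesis genes ASNS and PHGDH were lower at -1.48 ± 0.11 and -1.47 ± 0.08. Of 51 S phase genes 44 were lower with DAC (45 adjusted over the list alone), of 19 histone genes 11 were higher and 2 lower (12 and 3 adjusted over the list alone), and of 24 cholesterol genes 18 were higher (20 adjusted over the list alone). These lists had adjusted p = 0.0020, 0.0058 and 0.0049 with an estimated correlation. In total 2683 genes were higher and 1684 lower, and the 4367 became 2737 without DAC 5 µM replicate 2. With DAC at 120 nM, TKTL1 was higher than with Aza at 150 nM by 6.01 ± 0.18, and HS3ST1 was lower at -1.64 ± 0.21. There were 1118 higher and 875 lower genes. These became 1147 and 1194 without DAC 120 nM replicate 2. The total of 1993 became 1289 without DAC 120 nM replicate 1 and 1108 and 1029 without replicates 1 and 2 of Aza.

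Fold changes against the shared DMSO arrays were correlated across genes, which are not independent replicates. In 100 simulations of unchanged groups against such controls r had a median of 0.344 and the top of its 95% range at 0.810, and the covariance a median of 0.00310. Between G668684 and DAC, r was 0.980 for the higher and 0.948 for the lower doses, 0.909 and 0.843 with separate DMSO arrays for each, and the covariance 0.190 and 0.117. Between G669071 and DAC, r was 0.944 and 0.910, with split controls 0.874 and 0.791, and the covariance 0.181 and 0.0968. Between G669043 and Aza, r was 0.692 at 1500 nM and 0.426 at 150 nM, with split controls 0.536 and 0.164, and the covariance 0.0428 and 0.010. Between DAC and Aza, r was 0.559 at the higher and 0.475 at the lower doses, with split controls 0.477 and 0.293, and the covariance 0.0665 and 0.0239.

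The genes called in both of 2 such comparisons share the DMSO arrays as well. In the simulations of unchanged groups limma called 0 genes in both comparisons, and lists of the observed sizes, ranked by p, overlapped by the medians and the upper ends of the 95% range given here as simulated. Independent lists leave out the shared arrays, and the simulated lists leave out the effects, so neither is the value expected for real effects with shared controls. The simulations also leave out deviations shared by the arrays of a group, so they can understate false calls. For G668684 and DAC, 2895 genes were higher in both at the higher and 1707 at the lower doses, against 568 and 240 for independent lists and simulated medians of 1055.5 and 517.5 (upper ends 1981 and 1152.5). With separate DMSO arrays for each they numbered 2380.5 and 1322.5 (503.75 and 220 for independent lists with those calls, a value that follows each later count with separate arrays). Lower in both were 2228 and 1407, against 376 and 186 and simulated medians of 663.5 and 372 (upper ends 1572 and 990). Separate arrays gave 1707 (362) and 993 (167). For G669071 and DAC, 2494 and 1371 were higher in both, against 512 and 195 and simulated medians of 976.5 and 440 (upper ends 1835 and 1005). Separate arrays gave 2086 (456) and 1038 (184). Lower in both were 1895 and 1010, against 350 and 124 and simulated medians of 622 and 271.5 (upper ends 1505 and 758). Separate arrays gave 1516 (344) and 695 (115). For G669043 and Aza, 706 at 1500 nM and 71 at 150 nM were higher in both, against 86.2 and 1.32 and simulated medians of 237 and 8 (upper ends 638.5 and 53.05). Separate arrays gave 495.5 (94.3) and 38.2 (19.4). Lower in both were 444 and 4, against 53.8 and 0.133 and simulated medians of 147 and 1 (upper ends 419 and 12.5). Separate arrays gave 312 (55.3) and 3.5 (12.2), the latter under its independent value. For DAC and Aza, 959 and 172 were higher in both, against 264 and 23.2 and simulated medians of 540 and 70.5 (upper ends 1128 and 171). Separate arrays gave 808 (254) and 163 (36.9). Lower in both were 856 and 71, against 235 and 8.21 and simulated medians of 442.5 and 27.5 (upper ends 1115 and 73.5). Separate arrays gave 625 (222) and 73.8 (16.0). The numbers of DAC and Aza lay below the upper ends apart from the 172, as did the 4 of G669043 and Aza at 150 nM.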

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

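Of the tests weighed in this part, those of RNA quality, of probe sets that bind several transcripts and of a smaller dose were chosen only after the result was seen, while the outcomes for normalization were written down first.

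At 1500 nM, 384 genes differed between G669043 and Aza, and at 150 nM 12 did, which a difference between groups brought up. The list called at 1500 nM with an estimated correlation was that of cholesterol and fatty acid synthesis, whose median difference was 0.44, with SCD higher with G669043 by 1.33. In Aza at 1500 nM the list was lower by a median of -0.29 against DMSO. RNA quality could explain this if the list recovered with the beta-actin value as a covariate. The median stayed at -0.29 (adjusted p = 0.0013 by camera with an estimated correlation), and the difference between compounds was 0.34 (2.97e-05). The mean beta-actin value was 0.02 in Aza at 1500 nM and 0.09 in DMSO. The covariate could thus hardly move the median against DMSO, which does not exclude RNA quality there. Between the compounds the mean values were 0.20 in G669043 and 0.02 in Aza, and the median difference went from 0.44 to 0.34. As far as this value measures it, RNA quality was therefore not the whole cause of the difference between compounds. Probe sets that bind several transcripts were excluded as the whole cause of the fall with Aza. Without them the median was -0.28 over 17 genes (adjusted p = 0.0043 by camera with an estimated correlation). The axis that parts the DMSO pairs, described below, was not tested as a cause. Whether G669043 acted as a smaller dose of Aza stays open: the list's median in G669043 was -0.32 times that in Aza, against 0.833 for p53 targets and 0.862 for cancer-testis genes, but Aza at 150 nM itself gave -0.23, 0.45 and 0.175 times its values at 1500 nM, so a change of sign also came with a smaller dose.

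A signal in data that no comparison used came from the control probe set for Alu repeats. It was brighter than in DMSO by 0.30 ± 0.03 (log2, SE) with DAC at 5 µM, 0.18 at 120 nM, 0.28 with the higher dose of G669071, 0.30 and 0.16 with G668684 at 7 µM and 150 nM and 0.10 with Aza at 1500 nM (adjusted p = 0.043), and it was not called at 0.08 with the lower dose of G669071, 0.05 with G669043 at 1500 nM, -0.02 with Aza at 150 nM and -0.02 with G669043 at 150 nM (adjusted p = 0.13, 0.49, 0.92 and 0.72). Between doses it was higher by 0.13, 0.20 and 0.15 for DAC, G669071 and G668684 (adjusted p = 0.029, 0.0013 and 0.014) and by 0.12 and 0.07 for Aza and G669043, which were not called (0.086 and 0.39). RNA quality might account for it, but with the beta-actin value as a covariate the value with DAC at 5 µM was 0.30 ± 0.03. The mean beta-actin value was 0.11 in that group and 0.09 in DMSO, so this measure does not account for the signal. Other aspects of RNA quality were not tested. Normalization might too, but the smaller value under further normalization was 0.30 ± 0.03. The median of all probe sets with DAC at 5 µM lay only -0.02 from that of DMSO beforehand. Further scaling could thus hardly move the Alu value, and an effect of RMA itself was not tested. Alu repeats lie in many transcripts, so which RNA gave the signal is open.

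Of 7681 probe sets without a gene name, 622 were brighter than in DMSO in at least 1 of the 10 comparisons, and 106 in all 6 groups given DAC, G669071 or G668684. Dimmer ones outnumbered brighter ones in each of these 6 groups and with Aza at 1500 nM, as with DAC at 5 µM (548 and 409). Brighter ones were more numerous with Aza at 150 nM (25 and 6) and with G669043 at 1500 nM (116 and 84) and 150 nM (5 and 2).

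The DMSO level of 4 genes had a replicate far from the others: FMR1NB in replicate 1 (gap of 0.906 of the range, 3.43 against a mean of 3.63), UTP20 in replicate 4 (0.895, 8.59 against 8.41), S100A4 in replicate 1 (0.882, 11.16 against 11.32) and GJA1 in replicate 2 (0.846, 3.39 against 3.86). These were 4 of 272 genes and quality measures tested, where 13.6 were expected at 1 in 20.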

How the results depend on the processing

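Under the alternatives 16806 values of named genes and 4586 of lists stayed called in the same direction or stayed uncalled. Of the others 1033 and 273 lost the call, 16 and 138 gained it, and 40 and 3 turned direction. Direction was compared only where the value was called with the settings of the report or with the alternative. A turn is a change of sign, counted also where only 1 of the 2 values was called. It can thus be a lost call with a small value of the other sign. Of the counts and correlations 1407 stayed within the set bounds and 248 moved. Treated groups had 2 arrays, so a group with 1 left out was assumed to vary like the others, and without detection calls the limit set by background is unknown. The cause was not tested for the values that follow, except where fewer arrays or fewer probe sets are the alternative itself. DMSO replicates 1 and 2 alone, DMSO replicates 3 and 4 alone and the beta-actin covariate were chosen after seeing the data. Only counts that moved beyond 1.5 times are given below, and a count for a list is the number of the 10 comparisons against DMSO in which it was called. With the settings of the report these were 0 for interferon and cytokine, 1 for methylation machinery, 2 for stress response, apoptosis, neuronal and cholesterol, 3 for blood, 4 for intestinal and ribosome, 5 for antigen presentation, 6 for nucleoside and fibroblast, 7 for hypermethylated, keratinocyte and DNA repair, and 8 for G2/M genes.

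With no filter, calls of a list numbered 2 for methylation machinery and 4 for cholesterol genes. With a filter at 6, comparisons in which a list was called numbered 3 for antigen presentation genes. With the mean of a gene's probe sets, the count of calls of a list was 1 for interferon, 2 for methylation machinery, 4 for stress response and 5 for neuronal genes. PCDH7 turned to 0.15 in DAC 5 µM, 0.67 in G669071 higher dose, 0.12 in G668684 7 µM and 0.15 in G668684 150 nM. NOC2L turned to -0.019 in Aza 1500 nM.

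Without probe sets that can bind several transcripts, the genes called numbered 163 for Aza 150 nM, 1068 for G669043 1500 nM, 53 for G669043 150 nM, 1387 for the G668684 doses and 214 for G669043 1500 nM against Aza 1500 nM. Further counts were 102 for G669071 higher dose against DAC 5 µM and 59 for G669071 lower dose against DAC 120 nM. Lists were called in this many comparisons: 0 for antigen presentation, 0 for nucleoside, 1 for stress response, 0 for apoptosis, 0 for intestinal, 1 for fibroblast and 0 for blood genes. In addition there were 0 for neuronal genes. The lists called in a group numbered 9 for G669071 lower dose, 7 for Aza 1500 nM and 7 for G669043 150 nM. The median turned to -0.078 for the antigen presentation list in G668684 150 nM. UCHL1 turned to -0.065 in DAC 5 µM, -0.12 in DAC 120 nM, -0.045 in G669071 higher dose and -0.13 in G669071 lower dose. UCHL1 was at -0.17 in G668684 7 µM, -0.015 in G668684 150 nM, -0.065 in Aza 1500 nM and -0.055 in G669043 1500 nM. HLA-DPB1 turned to -0.12 in DAC 5 µM, -0.14 in DAC 120 nM and -0.015 in G668684 150 nM. ABHD12 turned to -0.058 in DAC 5 µM. KLK10 turned to -0.025 in DAC 5 µM and -0.14 in G669071 higher dose. CD79B turned to -0.040 in DAC 5 µM, -0.13 in G669071 higher dose and -0.015 in G668684 7 µM. RRP12 turned to -0.042 in DAC 5 µM, -0.082 in G669071 higher dose, -0.11 in G668684 7 µM and -0.032 in Aza 1500 nM. UCKL1 turned to -0.032 in DAC 120 nM, -0.17 in G669071 higher dose and -0.0075 in G668684 150 nM. IDI1 turned to -0.070 in DAC 120 nM, -0.11 in Aza 150 nM, -0.12 in G669043 1500 nM and -0.11 in G669043 150 nM. FAS turned to -0.043 in G669071 higher dose and -0.068 in G668684 7 µM. ASPM turned to 0.010 in Aza 1500 nM. NOC2L turned to -0.40 in Aza 1500 nM and -0.18 in G669043 1500 nM. CASP10 turned to 0.062 in G669043 1500 nM. GDF15 turned to -0.040 in G669043 150 nM.

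Without an intensity trend, the genes called numbered 77 for G669043 150 nM. Counts of calls per list were 1 for interferon, 3 for antigen presentation, 2 for methylation machinery and 1 for neuronal genes. With only the compared arrays, the genes called numbered 1576 for DAC 120 nM, 1155 for G669071 lower dose, 3846 for G668684 7 µM, 1782 for G668684 150 nM and 1305 for Aza 1500 nM. Also counted were 21 for Aza 150 nM, 315 for G669043 1500 nM, 0 for G669043 150 nM, 753 for the DAC doses and 4640 for the G669071 doses. The rest were 1335 for the G668684 doses, 2788 for the Aza doses, 1158 for the G669043 doses, 1200 for G669043 1500 nM against Aza 1500 nM and 1846 for G669043 150 nM against Aza 150 nM. To these add 958 for G669071 higher dose against DAC 5 µM, 0 for G669071 lower dose against DAC 120 nM and 481 for DAC 120 nM against Aza 150 nM. Calls of a list numbered 2 for antigen presentation and 2 for methylation machinery genes. With array weights, the genes called numbered 2415 for DAC 120 nM, 524 for Aza 150 nM, 91 for G669043 150 nM, 4194 for the G669071 doses and 2631 for the Aza doses. The rest were 1811 for the G669043 doses, 1265 for G669043 1500 nM against Aza 1500 nM, 621 for G669043 150 nM against Aza 150 nM, 896 for G669071 higher dose against DAC 5 µM and 62 for G669071 lower dose against DAC 120 nM. Lists were called in this many comparisons: 2 for methylation machinery genes.

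After quantile normalization, the genes called numbered 46 for G669043 150 nM, 589 for G669043 1500 nM against Aza 1500 nM and 155 for G669071 lower dose against DAC 120 nM. Comparisons in which a list was called numbered 1 for stress response, 1 for apoptosis, 2 for intestinal and 1 for cholesterol genes. Per group the lists called were 1 for G669043 150 nM. After centring, the genes called numbered 160 for Aza 150 nM, 680 for the Aza doses, 427 for the G669043 doses, 215 for G669043 1500 nM against Aza 1500 nM and 6 for G669043 150 nM against Aza 150 nM. Further counts were 83 for G669071 higher dose against DAC 5 µM and 49 for G669071 lower dose against DAC 120 nM.

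Replicate numbers 3 and 4 occur only in DMSO, so a replicate block takes those 2 arrays out of the comparisons with DMSO. It is therefore close to the setting of DMSO replicates 1 and 2 alone, given below, and not a separate check. With a replicate block, the genes called numbered 658 for Aza 150 nM, 3121 for G669043 1500 nM, 5380 for G669043 150 nM, 1768 for the Aza doses and 1431 for the G669043 doses. In addition there were 1068 for G669043 1500 nM against Aza 1500 nM, 112 for G669043 150 nM against Aza 150 nM, 4 for G668684 150 nM against DAC 120 nM, 328 for G669071 higher dose against DAC 5 µM and 234 for G669071 lower dose against DAC 120 nM. The count of calls of a list was 1 for interferon, 0 for antigen presentation, 3 for methylation machinery, 0 for nucleoside, 1 for intestinal, 4 for keratinocyte and 2 for fibroblast genes. Also counted were 1 for blood, 1 for neuronal and 6 for cholesterol genes. By group the list calls came to 7 for G669071 lower dose, 10 for G668684 150 nM and 7 for Aza 150 nM. The higher and lower genes with the block were 57 and 55 for G669043 150 nM against Aza 150 nM, 1614 and 1207 for Aza 1500 nM and 3826 and 3828 for DAC 5 µM, which turned the larger side. Equal replicate numbers did not pair across all treated groups: of 45 pairs of groups 17 correlated above 0.1, with a lowest r of -0.39, a median of 0.02 and a highest of 0.61. Whether the numbers mark a batch in part of the groups is open, and the block is given for completeness.

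With an estimated correlation, counts of calls per list were 4 for hypermethylated, 0 for antigen presentation, 2 for G2/M, 0 for DNA repair, 0 for methylation machinery, 0 for nucleoside and 0 for stress response genes. To these add 0 for apoptosis, 0 for intestinal, 4 for keratinocyte, 0 for fibroblast, 0 for blood, 0 for neuronal and 1 for cholesterol genes. Further counts were 0 for ribosome genes. The lists called in a group numbered 7 for DAC 120 nM, 8 for G669071 higher dose, 5 for G669071 lower dose, 6 for G668684 150 nM and 5 for Aza 1500 nM. In addition there were 0 for Aza 150 nM, 3 for G669043 1500 nM and 0 for G669043 150 nM. With split controls, the correlations of fold changes were 0.164 for G669043 150 nM and Aza 150 nM, 0.909 for G668684 7 µM and DAC 5 µM, 0.843 for G668684 150 nM and DAC 120 nM, 0.874 for G669071 higher dose and DAC 5 µM, 0.791 for G669071 lower dose and DAC 120 nM and 0.293 for DAC 120 nM and Aza 150 nM.

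Against DMSO replicates 1 and 2 alone, the genes called numbered 547 for Aza 150 nM, 2788 for G669043 1500 nM and 5084 for G669043 150 nM. Calls of a list numbered 1 for interferon, 0 for antigen presentation, 3 for methylation machinery, 0 for nucleoside, 1 for intestinal, 4 for keratinocyte and 2 for fibroblast genes. Also counted were 1 for blood, 1 for neuronal and 6 for cholesterol genes. Per group the lists called were 7 for G669071 lower dose, 10 for G668684 150 nM and 7 for Aza 150 nM. Against DMSO replicates 3 and 4 alone, the genes called numbered 4988 for G669071 lower dose, 5504 for Aza 1500 nM, 1270 for Aza 150 nM and 2501 for G669043 1500 nM. Comparisons in which a list was called numbered 3 for methylation machinery, 5 for stress response, 0 for apoptosis, 8 for intestinal and 5 for blood genes. By group the list calls came to 17 for DAC 5 µM, 10 for Aza 150 nM, 12 for G669043 1500 nM and 4 for G669043 150 nM. The median turned to -0.12 for the G2/M list in Aza 150 nM and -0.097 for the DNA repair list in Aza 150 nM. With the beta-actin value as a covariate, the genes called numbered 588 for Aza 150 nM, 1224 for G669043 150 nM, 2581 for the G669071 doses, 1762 for the Aza doses and 2770 for the G669043 doses. The rest were 248 for G669043 1500 nM against Aza 1500 nM, 4 for G668684 150 nM against DAC 120 nM, 271 for G669071 higher dose against DAC 5 µM and 272 for G669071 lower dose against DAC 120 nM. The count of calls of a list was 1 for interferon, 3 for antigen presentation, 2 for methylation machinery, 1 for intestinal, 1 for neuronal and 4 for cholesterol genes. The lists called in a group numbered 7 for Aza 150 nM.

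When 1 array was left out in turn, the genes called ranged over 1309 to 3081 for G669071 lower dose, 2239 to 4023 for G668684 150 nM, 1643 to 3577 for Aza 1500 nM and 56 to 393 for Aza 150 nM. Under the same the range was 576 to 1687 for G669043 1500 nM, 3 to 961 for G669043 150 nM, 1444 to 3316 for the DAC doses and 16 to 45 for G669071 higher dose against DAC 5 µM. Other ranges of this kind were 2737 to 3352 for DAC 5 µM against Aza 1500 nM, 13 to 77 for G669071 lower dose against DAC 120 nM, 1029 to 2341 for DAC 120 nM against Aza 150 nM and 725 to 890 for the G669071 doses. Ranges for further contrasts were 1049 to 1690 for the G668684 doses, 339 to 633 for the Aza doses, 47 to 197 for G669043 1500 nM against Aza 1500 nM and 5 to 9 for G669043 150 nM against Aza 150 nM. The last range was 230 to 256 for the G669043 doses. The calls of a list ranged over 0 to 1 for interferon, 3 to 6 for antigen presentation, 1 to 3 for methylation machinery, 1 to 3 for stress response and 1 to 2 for apoptosis genes. For other lists they covered 1 to 4 for blood, 1 to 3 for neuronal, 0 to 1 for cytokine and 2 to 5 for cholesterol genes. The lists called in a group ranged over 1 to 4 for Aza 150 nM and 8 to 13 for G669043 150 nM.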

Other observations

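In this part, the test of the higher-dose genes and the relations of the array axis were chosen only after the result was seen, while the outcomes for the axis and G669043 were written down first.

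KRT20, a keratin of differentiated colon epithelium, rose by 3.69 ± 0.10 and 2.51 ± 0.10 (log2 fold change ± SE, 2 arrays against 4) with the higher and lower dose of G669071, by 3.15 ± 0.10 and 2.77 ± 0.10 with G668684 at 7 µM and 150 nM, and by 1.20 ± 0.10 with Aza at 1500 nM. S100A2, from the keratinocyte list, rose by 1.68 ± 0.07 with DAC at 5 µM, 1.09 ± 0.07 with Aza at 1500 nM and 0.64 ± 0.07 with Aza at 150 nM. The uridine phosphorylase UPP1 rose by 1.87 ± 0.11 with Aza at 1500 nM and 0.74 ± 0.11 at 150 nM.

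With G669043 at 150 nM, 157 genes and 13 lists were called while the largest fold change was 0.92 and the median 0.37. These changes may come from where the arrays lie on the axis that parts DMSO replicates 1 and 2 from 3 and 4. The fold changes correlated with its loadings at r = 0.658, against an absolute r of at most 0.317 in the other comparisons, which fits. A smaller form of the response at 1500 nM fits too: genes raised at least 2-fold there against 2 DMSO arrays (71 to 102 genes over the 6 splits) had a median of 0.14 at 150 nM against the other 2 (0.098 to 0.160), where that of all genes was -0.010 to 0.015. Not all lists followed the higher dose by the preset. S phase genes were called lower at 1500 nM and higher at 150 nM, and cancer-testis genes were called at 1500 nM only. The p53 targets were called higher at both doses. The data do not separate these explanations. The mean beta-actin value of the group was 0.09, and that of DMSO 0.09.

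This axis held 45.9% of the variance within groups. Across the 24 arrays, as deviations from group means with 13 degrees of freedom, it correlated with the beta-actin 3 prime minus 5 prime value at r = 0.797 (exact permutation within groups, p = 0.013), a Spearman correlation of 0.781 (p = 0.019), and 0.779 without the 2 arrays farthest out. With the Alu control r was -0.696 (p = 0.094), the Spearman correlation -0.611 (p = 0.057), and r without the 2 arrays farthest out -0.592, which did not pass. Adjusted over both relations the p-values were 0.026 and 0.094 for r and 0.038 and 0.057 for the Spearman correlations. The GAPDH 3 prime minus 5 prime value, which did not part the DMSO pairs, was not set against the axis. The beta-actin value was highest in G669043 at 1500 nM, at 0.20 ± 0.19 (SD, n = 2), and lowest in G668684 at 150 nM, at -0.03 ± 0.06 (SD, n = 2). The former rank rests on replicate 2, at 0.34, since replicate 1 was at 0.07. Fold changes against DMSO followed the axis loadings at r = -0.317 with Aza and 0.171 with G669043, both at 1500 nM. Whether the axis added to the difference between these compounds in cholesterol genes was not tested. The 2 arrays of DAC at 120 nM lay at -15.95 and 15.95 on the axis, and those of G668684 at 150 nM at -9.12 and 9.12.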
